A study of Caenorhabditis elegans with 15 samples.

How the data were processed

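RNA was taken from synchronised larvae of the wild type and 4 mutant strains, and 5 microgram of total RNA per sample was labelled with biotin in the standard Affymetrix reaction for expression arrays. The series describes the replicates as separately grown populations, except that replicate 2 of the zfp-1 strain and replicate 2 of the lin-35 unc-13 strain were each hybridised to 2 arrays. The deposited values are on a log2 scale, and per the labels the authors made them with GCRMA, which corrects the background by probe GC content, normalises between arrays and summarises each probe set. The version of GCRMA and its settings are not given in the sources used here. Between the 15 arrays, deposited values ran from 1.42 to 17.0 and medians from 4.48 to 4.86. Arrays have no read depth; their number limits the precision.

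The table held 22625 probe sets, of which 77 Affymetrix controls were left out. The annotation gave exactly 1 gene for 20766 probe sets, several genes for 887, and did not list 895; the last 2 kinds were set aside. Gene IDs of 20701 probe sets matched the RefSeq table of assembly WBcel235, which was used for names, chromosomes and neighbours; no genome build is named for the arrays, so no coordinates are given. Among 17118 genes, 2981 had more than 1 probe set, and the probe set with the highest mean over the samples was kept. Genes were tested if their value was at least 5 in at least 2 of the 13 biological samples, which left 8653 genes. A gene below 5 in all other groups could thus enter through 1 group in which it was high. Counts and list tests for that group are then conditioned on its level there. Among the called genes with further probe sets above this value, a probe set of the opposite sign was seen in 0 of 39 genes for alg-1, 0 of 52 for zfp-1, 7 of 197 for rde-4 and 8 of 85 for lin-35.

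Arrays of the same biological sample were averaged. All 5 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, 8 residual and 3.49 prior degrees of freedom), so that groups of 2 borrow their spread from the others, with a median residual SD of 0.32. Each mutant was contrasted with wild type and each pair of mutants directly, two-sided, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. SE in the text is limma's standard error of a log2 change. Where a group lay wholly below 5, folds were computed against 5 and given as a lower bound, while the tests and the medians of gene lists used the deposited values as they are. Where only some samples of a group lay below 5, the change is given with their number.

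Gene lists were fixed before the data were examined, as were the fits, the threshold, the alternatives and the rule for named genes. There were 33 lists, of which 7 hold markers of cell types or older animals, and 6 lists of the genes of each chromosome; 4 of 433 listed names were not matched. Lists with at least 3 genes tested were compared with all other genes by camera with a preset correlation of 0.01, adjusted over lists within a mutant. camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. The named genes are the 10 largest rises and 10 largest falls per mutant among genes that passed and whose mutant samples all lay beyond all wild-type samples, the 5 mutated genes, up to 4 members of each list with the smallest adjusted p under 0.05, the 15 largest shared rises and 10 largest shared falls, and the 3 largest differences each way between mutants. Genes named outside this rule are marked as chosen after their values were seen.

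The pipeline was tested on simulated data with 8653 genes. Of genes given a log2 change of 1, 41% were recovered for alg-1, 23% for zfp-1, 43% for rde-4 and 29% for lin-35; of those given a change of 2, 85%, 88%, 81% and 77% were recovered. The simulated fits made 3, 4, 7 and 7 false calls. Their noise was normal and independent between genes, and no wild-type sample stood apart as in the real data. They therefore do not measure the false calls of the real fits. Sharing of changes was compared with 100 simulations of unchanged groups set against the same simulated wild-type samples. The residuals of whole samples were drawn with replacement, so 1 sample's residuals could enter several groups. With 3 wild-type samples the controls were not divided between comparisons.

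Alternatives covered quantile normalisation of the deposited values, subtraction of array medians, filters on dim genes, the handling of arrays from the same sample, fits of a mutant and wild type alone, the replicate number as a block, the variance prior, probe sets in place of genes, thresholds, the set tests and the omission of each biological sample in turn. Added after the data were seen were a fit with alg-1 replicates 1 and 3 as a single sample and a fit with wild-type replicate 3 as the only control. Figures were drawn with matplotlib 3.10.9.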

Results

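Transcript levels were measured in Caenorhabditis elegans larvae on 15 arrays covering 13 biological samples. The wild type was the Bristol strain N2, with 3 separately grown populations. There were 3 populations of alg-1 mutants, which lack an Argonaute protein of the microRNA pathway, and 3 of rde-4 mutants, which lack a double-stranded RNA-binding partner of Dicer. There were 2 populations of zfp-1 mutants, which carry a deletion in a PHD zinc finger gene, and 2 of a lin-35 unc-13 strain. lin-35 encodes the only retinoblastoma family protein of the worm and unc-13 a synaptic vesicle priming factor, so the effects of the 2 mutations cannot be separated, and the strain is called the lin-35 mutant for short. All animals hatched without food and were then fed for 6 to 7 h. Each array held between 8140 and 8400 genes at a log2 value of 5 or more, and the number of arrays limits the precision of every value. Wild-type replicates 1 and 2 lay apart from replicate 3 on the second principal component, at 46.1 and 49.3 against 13.6, and all mutant samples lay between -30.9 and 21.9.

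**Figure D1:**
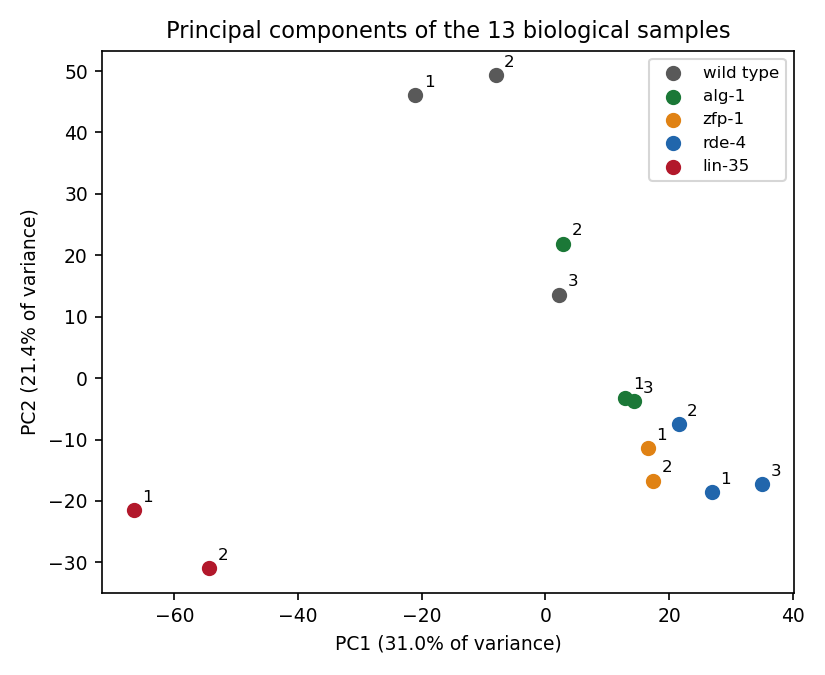
Scores of the 13 biological samples on the first and second principal components of the log2 values of 8653 genes, with the replicate number beside each point. The lin-35 samples lie at -66.6 and -54.4 on the first component, and wild-type replicates 1 and 2 lie at 46.1 and 49.3 on the second.

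The transcripts of the mutated genes were compared first, as a check of the strains. The rde-4 transcript fell from 10.59 ± 0.15 (SD, n = 3) in wild type to 7.61 ± 0.12 (n = 3) in the rde-4 mutant (limma adjusted p = 6.1e-06), and in the lin-35 mutant it rose by 1.2 (limma adjusted p = 0.0027). The lin-35 transcript fell by 1.61 in the lin-35 mutant, from 9.46 ± 0.15 (n = 3) to 7.86 ± 0.54 (n = 2, limma adjusted p = 0.0015). In their own mutants the log2 differences from wild type were -1.44 ± 0.58 (SE) for alg-1, 0.01 ± 0.22 for zfp-1 and -0.14 ± 0.18 for unc-13, and none of these passed the test. The alg-1 value rested largely on alg-1 replicate 2, at 6.28 against 8.35 and 8.70 in replicates 1 and 3, and was -0.69 without it. Where the probes lie relative to each lesion is not given in the sources used here.

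The question in the title of the study is whether endogenous siRNA targets are held down by RNAi factors and by a retinoblastoma-related gene. Of 20 target names listed from memory before the data were examined, 13 had a probe set and 6 were expressed highly enough to be tested. E01G4.5, a known target of the endogenous siRNA pathway, rose from 6.43 ± 0.34 (SD, n = 3) in wild type to 9.29 ± 0.39 (n = 3) in the rde-4 mutant, a change of 2.85 ± 0.29 (SE, limma adjusted p = 0.00029). It fell in the lin-35 mutant to 4.63 ± 0.28 (n = 2), at least 2.70-fold lower (limma adjusted p = 0.0051), and the direct difference between the rde-4 and lin-35 mutants passed the test. In the zfp-1 mutant W04B5.1 fell by 1.08 ± 0.19 (limma adjusted p = 0.012). The median log2 change of the 6 genes was 0.68 in the rde-4 mutant, -0.38 in the alg-1 mutant, -0.96 in the zfp-1 mutant and -0.23 in the lin-35 mutant. Counts of genes that passed, adjusted over the list alone, were 3 higher in the rde-4 mutant, 3 lower in alg-1, 4 lower in zfp-1 and 2 lower in lin-35. As a set against all other genes, the list was shifted down in the zfp-1 mutant (camera adjusted p = 0.018), with adjusted p = 0.424 with an estimated correlation. The camera adjusted p was 0.052 in the rde-4 mutant, 0.081 in alg-1 and 0.118 in lin-35, while the fry adjusted p was 0.0028 upwards in rde-4, 0.0063 downwards in zfp-1, 0.0339 downwards in lin-35 and 0.166 downwards in alg-1. A list of 6 genes recalled from memory does not stand for all siRNA targets.

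**Figure D2:**
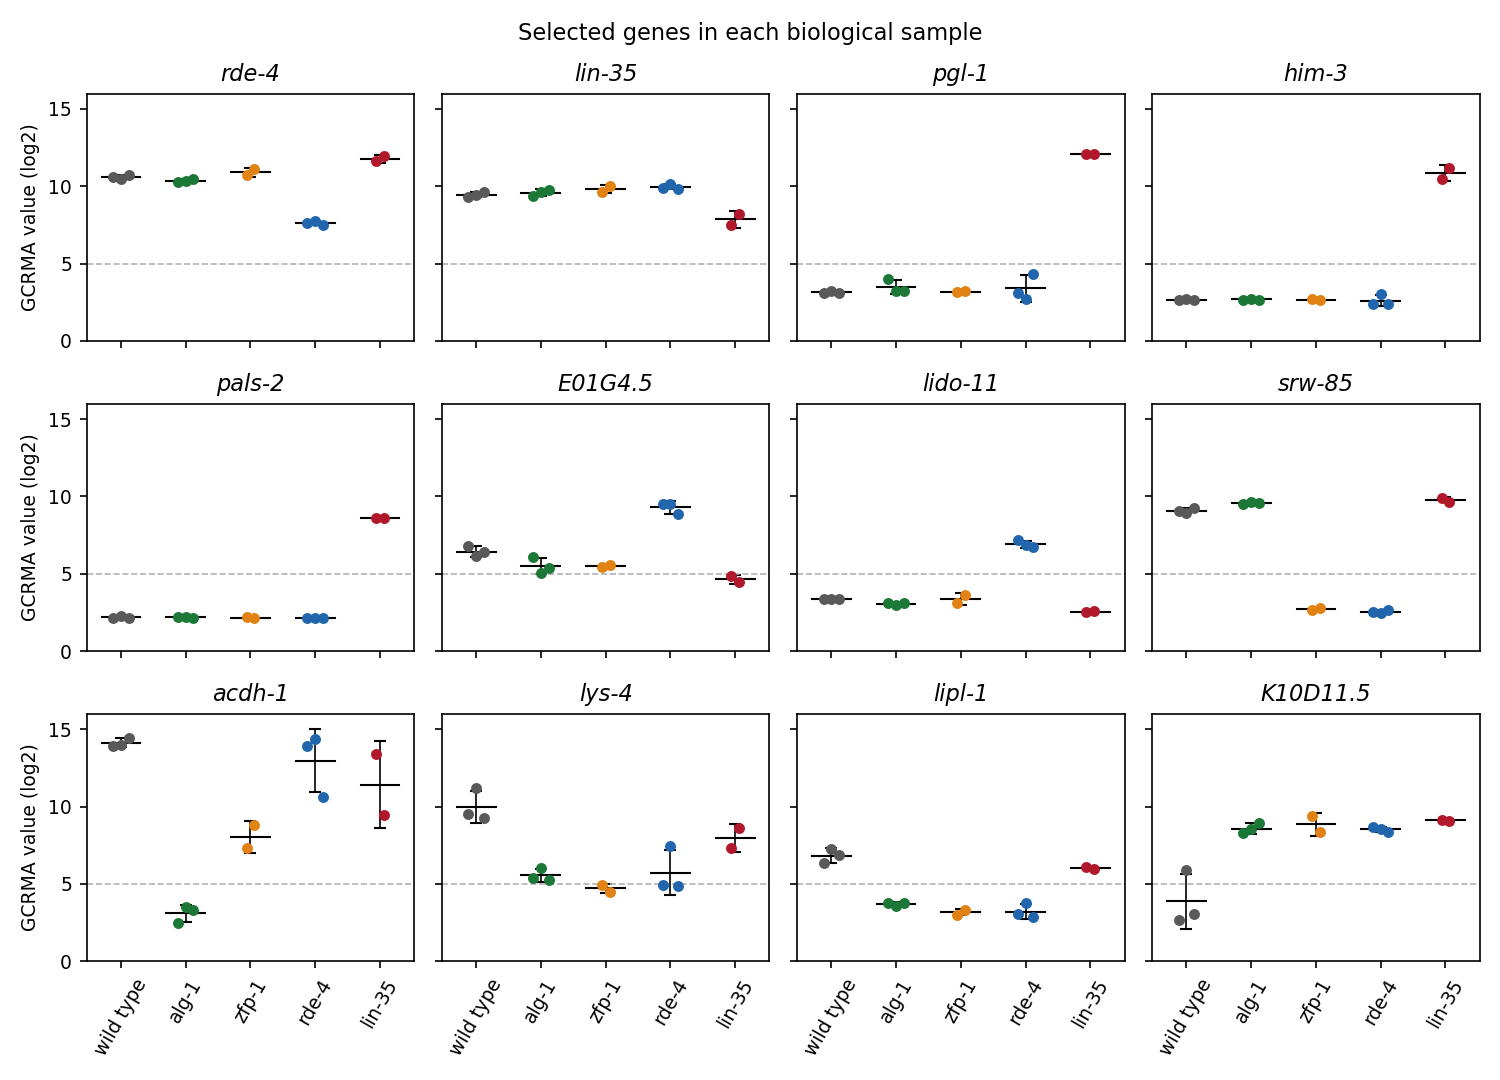
Log2 GCRMA value of 12 genes in each of the 13 biological samples, with points for samples, a bar at the group mean and an error bar of 1 SD; the dashed line is at 5, the value used in the filter. E01G4.5 lies at 9.29 in the rde-4 mutant against 6.43 in wild type, and pgl-1 lies at 12.09 in the lin-35 mutant against 3.15.

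The comparison of the alg-1 mutant with wild type asked which transcripts depend on this microRNA Argonaute. The largest fall was that of acdh-1, an acyl-CoA dehydrogenase of the propionate breakdown shunt, from 14.12 ± 0.30 (SD, n = 3) to 3.09 ± 0.56 (n = 3, limma adjusted p = 0.00025), at least 558-fold lower. In the same direction hphd-1, another enzyme of the shunt, fell by 4.71 ± 0.68 (SE) and the nuclear hormone receptor nhr-68 fell by 4.33 ± 0.67. The uncharacterised genes C23G10.11 and T05E12.6 fell by 6.41 and 6.32, with 2 and 1 of 3 alg-1 samples below 5, and DH11.2 was at least 16.3-fold lower. Among the rises were K10D11.5 at 4.7 ± 0.65, with 2 of 3 wild-type samples below 5, B0348.2 at 2.86 ± 0.34, the degenerin channel gene acd-1 at least 1.35-fold, the sphingomyelinase gene asm-3 at least 3.1-fold and the small GTPase gene rab-11.2 at least 1.37-fold (limma adjusted p = 0.00017).

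Of the 27 fat metabolism and fasting genes tested, 3 fell and 0 rose, or 7 and 0 adjusted over the list alone. They were the lysosomal lipase gene lipl-1, which was at least 3.55-fold lower, the lipid-binding protein gene lbp-1, which fell by 2.24, and the enoyl-CoA hydratase gene ech-6, which fell by 1.89 (camera adjusted p = 0.00024 for the list, with adjusted p = 0.304 with an estimated correlation). The isocitrate lyase gene icl-1 of the glyoxylate cycle fell by 2.76. The intestinal markers cpr-6, ftn-1 and ges-1 fell by 2.03, 2.07 and 1.54, and the intestinal list of 14 genes was not shifted (camera adjusted p = 0.487). Among 122 nuclear hormone receptors 2 rose and 5 fell, or 2 and 7 adjusted over the list alone; nhr-23, a regulator of molting, rose by 1.69 ± 0.36 (SE) and nhr-101 fell by 2.48 (list camera adjusted p = 3.1e-05, adjusted p = 0.813 with an estimated correlation). Of 39 antimicrobial genes 1 rose and 4 fell, or 2 and 9 adjusted over the list alone, in which the lysozyme gene lys-4 fell by 4.43 and lys-1 rose by 0.87. Of 75 neuropeptide genes 6 fell, or 11 with 1 rise adjusted over the list alone, and nlp-10 fell by 1.54 ± 0.20. Of 61 cuticle collagens 2 fell, col-91 by 1.28 and col-80 by 1.44, with the same count adjusted over the list alone. These 3 lists were shifted down (camera adjusted p = 0.00123, 0.00123 and 0.000507), each with adjusted p = 0.874 with an estimated correlation.

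In all, 93 genes rose and 178 fell in the alg-1 mutant at an adjusted p under 0.05 (limma, 8653 genes). Replicates 1 and 3 of the alg-1 mutant differed about as little as the 2 arrays of a single sample (SD of the difference 0.27 against 0.22 and 0.36), and 67 genes passed when they were taken as 1 sample. With wild-type replicate 3 as the only control 16 genes passed. The majority of falls was lost without wild-type replicate 3, where 252 genes rose and 244 fell. The count was 147, 86 or 496 without wild-type replicate 1, 2 or 3, 67 or 80 without alg-1 replicate 1 or 3, 167 without either zfp-1 replicate and 180 without rde-4 replicate 1, against 271 with all samples.

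**Figure D3:**
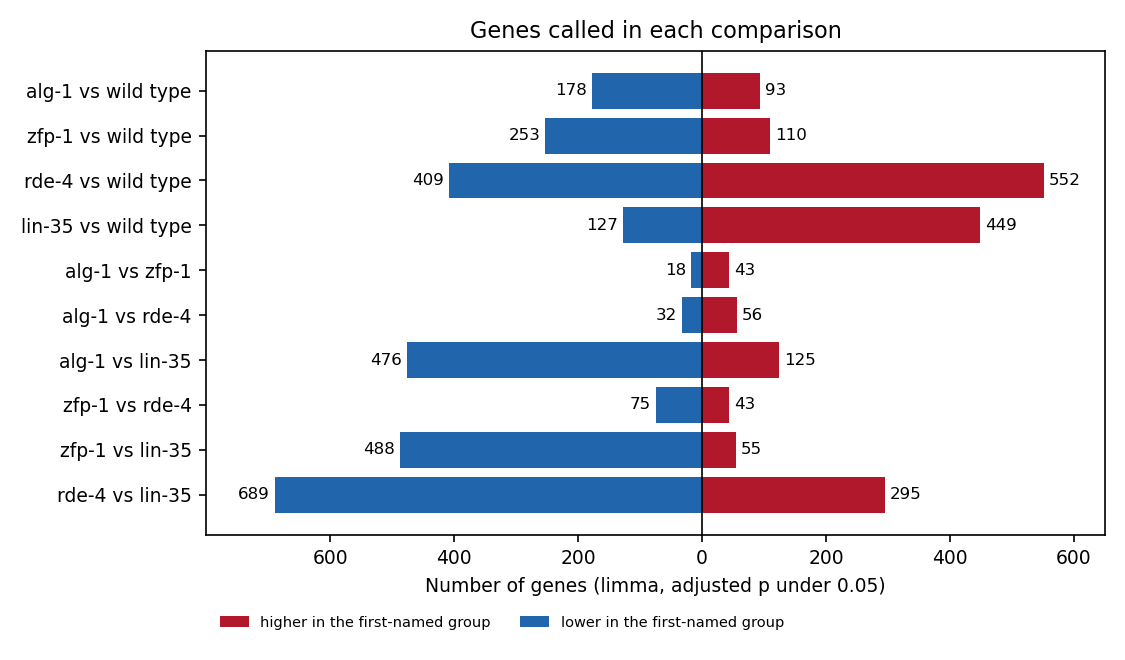
Number of genes higher (red, to the right) and lower (blue, to the left) at a limma adjusted p under 0.05 in each of the 10 comparisons, out of 8653 genes tested. The rde-4 mutant has the most genes apart from wild type, 552 higher and 409 lower, and the comparison of the alg-1 and zfp-1 mutants has the fewest, 43 and 18.

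In the zfp-1 mutant, the gene with the smallest p was srw-85, a member of a chemoreceptor family. It fell from 9.07 ± 0.16 (SD, n = 3) in wild type to 2.70 ± 0.10 (n = 2), at least 16.8-fold lower (limma adjusted p = 2.4e-09). The lysozyme genes lys-4 and lys-7 were at least 31.7-fold and 10.6-fold lower, acdh-1 fell by 6.07 ± 1.15 (SE), and nhr-68 fell by 3.83. The cathepsin B-like protease gene cpr-6 fell by 3.79 ± 0.26 (limma adjusted p = 3.7e-05), whereas its relative cpr-2 rose by 3.09 ± 0.51, with 2 of 3 wild-type samples below 5. Other rises were K10D11.5 at 4.98, dod-22, a gene downstream of the insulin pathway factor DAF-16, at 3.76 ± 0.49, R13A5.7 at 3.43 ± 0.29, ZK742.3 at least 3.63-fold and the insulin pathway kinase gene pdk-1 at 2.31 ± 0.34.

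Of 75 neuropeptide genes 9 fell in the zfp-1 mutant and 0 rose, or 17 and 0 adjusted over the list alone, among them flp-21, which fell by 2.93, and flp-12, which fell by 2.46 (camera adjusted p = 2.3e-07, adjusted p = 0.555 with an estimated correlation). Of 39 antimicrobial genes 7 fell, or 13 adjusted over the list alone, including the lysozyme gene ilys-5, which fell by 2.5 (camera adjusted p = 1.1e-06, adjusted p = 0.555 with an estimated correlation). Of 27 fat metabolism genes 6 fell, with the same count adjusted over the list alone; lipl-1 was at least 3.55-fold lower and hacd-1, a fatty acid oxidation gene, fell by 2.65 (camera adjusted p = 0.0055, adjusted p = 0.424 with an estimated correlation). Of 14 intestinal markers 3 fell, or 4 adjusted over the list alone, with ftn-1 falling by 2.65 and ges-1 by 1.74 (camera adjusted p = 0.0734, fry adjusted p = 0.0182 downwards). The 27 DNA replication genes were shifted up with mcm-4 alone passing the test, at 0.97 (camera adjusted p = 0.018, adjusted p = 0.698 with an estimated correlation). The 20 histone genes were shifted down with 0 passing, also when adjusted over the list alone (camera adjusted p = 0.018, adjusted p = 0.68 with an estimated correlation). At an adjusted p under 0.05, 110 genes rose and 253 fell (limma). With only 2 populations, the count rested on each: 49 or 51 genes passed without zfp-1 replicate 1 or 2, and 198, 135 or 854 without wild-type replicate 1, 2 or 3. Without wild-type replicate 3, 430 rose and 424 fell, so the majority of falls was lost. With wild-type replicate 3 as the only control 21 genes passed.

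In the rde-4 mutant, lido-11 rose from 3.38 ± 0.01 (SD, n = 3) to 6.90 ± 0.25 (n = 3), at least 3.74-fold higher (limma adjusted p = 1.7e-06), C46F2.1 was at least 3.24-fold higher and ppat-1 rose by 2.63 ± 0.35 (SE). The mitochondrial chaperonin gene hsp-60 rose by 2.39 ± 0.59 and the mitochondrial insertase gene oxa-1 by 2.70 ± 0.60. srw-85 fell to 2.55 ± 0.09 (n = 3), at least 16.8-fold lower (limma adjusted p = 5.1e-10), as in the zfp-1 mutant. C23G10.11 was at least 62.1-fold lower, and F46C5.1, T22F3.11 and F11A5.9 fell by 6.08, fell by 5.88 and fell by 5.74, with 0, 1 and 2 of 3 rde-4 samples below 5. The alcohol dehydrogenase gene adh-1 fell by 4.39 ± 0.30 (limma adjusted p = 1.3e-05), and the gut protease genes cpr-1 and cpr-6 fell by 4.22 ± 0.47 and 2.57 ± 0.23.

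Neuropeptides made up the list with the most falls in the rde-4 mutant: 25 of 75 fell and 0 rose, or 40 and 1 adjusted over the list alone, including flp-12, which fell by 2.66 ± 0.34, and nlp-9, which fell by 1.47 (camera adjusted p = 3.5e-14, adjusted p = 0.314 with an estimated correlation). Of 44 C-type lectins 6 fell, or 9 adjusted over the list alone, with clec-17 falling by 2.33 and clec-76 by 2.44 (camera adjusted p = 2.9e-05, adjusted p = 0.102 with an estimated correlation). Of 39 antimicrobial genes 8 fell, or 11 adjusted over the list alone, and lys-7 was at least 10.6-fold lower. Of 27 fat metabolism genes 8 fell, or 10 adjusted over the list alone, with lipl-1 at least 3.55-fold lower and the lipase gene lipl-2 falling by 2.19. Of 14 intestinal markers 4 fell, with the same count adjusted over the list alone, and ges-1 fell by 2.42 ± 0.30. Of 122 nuclear hormone receptors 2 rose and 13 fell, with the same counts adjusted over the list alone; nhr-19 fell by 1.96. These 4 lists were shifted down (camera adjusted p = 1.5e-05, 0.0041, 0.0047 and 3.1e-05), each with adjusted p = 0.314 with an estimated correlation. Of 61 collagens 6 fell, with the same count adjusted over the list alone, col-107 by 1.95 (camera adjusted p = 1.1e-08, adjusted p = 0.419 with an estimated correlation). Of 37 F-box genes 1 rose and 5 fell, with the same counts adjusted over the list alone, with fbxa-5 at least 1.34-fold lower (camera adjusted p = 0.00085, adjusted p = 0.394 with an estimated correlation). Of 14 insulin pathway genes 1 rose and 3 fell, or 1 and 6 adjusted over the list alone, with dod-3 falling by 2.63 and pdk-1 rising by 1.52 (camera adjusted p = 0.0386, adjusted p = 0.314 with an estimated correlation). The 20 histone genes were shifted down with his-71 alone passing, which fell by 0.80 (camera adjusted p = 0.0067, adjusted p = 0.571 with an estimated correlation).

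The rde-4 mutant had 552 rises and 409 falls (limma, adjusted p under 0.05). The array of rde-4 replicate 2 had a 3′ to 5′ log2 difference of 2.96 for actin and 1.11 for GAPDH control probe sets, the highest of the 15 arrays. For actin the rde-4 arrays lay at 1.94 to 2.96, wild type at 1.25 to 2.22 and the other mutants at 0.81 to 1.79. For GAPDH the ranges were 0.56 to 1.11 in rde-4 and 0.49 to 0.81 in wild type. RNA quality is thus partly confounded with the rde-4 group, which omitting replicate 2 does not resolve. The majority of rises was not stable. Falls were the majority without rde-4 replicate 1 (173 rises, 237 falls) or 2 (262, 306), without wild-type replicate 1 (84, 146) or 2 (92, 156), and with wild-type replicate 3 as the only control (9, 24). They were also the majority without a filter (172, 204), with only the mutant and wild type in the fit (80, 115) and at an adjusted p under 0.01 (51, 100). The total was 410 or 482 without rde-4 replicate 1 or 3, 591 without either zfp-1 replicate, 230, 248 or 1452 without wild-type replicate 1, 2 or 3, and 33 with wild-type replicate 3 as the only control, against 961.

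In the lin-35 mutant, some genes of the germ line were expressed at levels far above wild type, while others of the same lists did not pass. The P granule genes pgl-1 and pgl-3 rose from 3.15 ± 0.05 and 2.98 ± 0.27 (SD, n = 3) to 12.09 ± 0.01 and 10.80 ± 0.04 (n = 2), at least 136-fold and 55.7-fold higher (limma adjusted p = 1.3e-08 and 7.1e-11). The Vasa-like helicase gene glh-1 rose by 7.05 ± 0.44 (SE), with 1 of 3 wild-type samples below 5, the meiotic chromosome axis gene him-3 at least 57.8-fold, the synaptonemal complex gene syp-1 at least 14.5-fold and the gonadal innexin gene inx-22 at least 55.3-fold. The germline nuclear Argonaute gene hrde-1 was at least 7.75-fold higher, and the eggshell proteoglycan gene cpg-2 at least 7.1-fold. Of the 449 rises, 136 started below a value of 5 in every wild-type sample. Of 9 meiotic genes tested 5 rose, with the same count adjusted over the list alone (camera adjusted p = 8.4e-06, adjusted p = 0.148 with an estimated correlation). Of 24 meiotic genes with a probe set, 5 were at or above 5 in every wild-type sample and 9 in every lin-35 sample. Members below 5 in all other groups were tested only if high in lin-35, so this share and test are conditioned on the rise. The same holds for the germ granule and RNAi factor lists below. Of 30 members with a probe set in each, 9 and 24 were at or above 5 in every wild-type sample and 12 and 26 in every lin-35 sample. Of 13 germ granule genes 5 rose, or 6 adjusted over the list alone; the median of the list was -0.35 and the mean 1.77, and the test for the list was upwards (camera adjusted p = 0.0361, adjusted p = 0.642 with an estimated correlation). Of 26 RNAi factors 4 rose, or 9 adjusted over the list alone: hrde-1, rde-4, the Tudor domain gene ekl-1 at 0.99 and the exonuclease gene mut-7 at 1.68, with 1 of 3 wild-type samples below 5 (camera adjusted p = 0.0185, adjusted p = 0.605 with an estimated correlation).

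The intracellular pathogen response, a set of genes known to be induced by microsporidia and viruses, had 14 of 21 members higher, or 16 adjusted over the list alone, with a median change of 4.15. Of 31 members with a probe set, 5 were at or above 5 in every wild-type sample and 19 in every lin-35 sample. Members below 5 in all other groups were tested only if high in lin-35. The count, the median and the tests of this list are therefore conditioned on the rise. pals-2 rose from 2.19 ± 0.05 (SD, n = 3) to 8.60 ± 0.02 (n = 2), at least 12-fold, and pals-38 and pals-33 were at least 11.9-fold and 6.61-fold higher. This list passed with camera at adjusted p = 8.4e-26 and was the only list of any mutant to pass with an estimated correlation, at adjusted p = 0.0059. Of 37 F-box genes 8 rose and 1 fell, with the same counts adjusted over the list alone, and fbxa-6 was at least 11-fold higher (camera adjusted p = 0.0134, adjusted p = 0.642 with an estimated correlation). Of 25 BTB and MATH genes 5 rose, or 6 adjusted over the list alone (camera adjusted p = 0.00039, adjusted p = 0.597 with an estimated correlation). Among them bath-5 was at least 2.14-fold higher and was tested through lin-35 alone. The F-box and the BTB and MATH tests are thus conditioned on the rise as well. At or above 5 in every wild-type sample were 29 F-box and 20 BTB and MATH genes, against 34 and 24 in every lin-35 sample. Of 27 glutathione S-transferases 2 rose, with the same count adjusted over the list alone, gst-16 by 1.88 and gst-6 by 1.30 (camera adjusted p = 0.0386, adjusted p = 0.71 with an estimated correlation).

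Among 30 cell cycle genes 15 rose and 2 fell in the lin-35 mutant, or 19 and 2 adjusted over the list alone. The Aurora B kinase gene air-2 rose by 2.33 ± 0.37 (SE), its chromosomal passenger partners csc-1 and icp-1 by 2.06 and 1.41, and the cyclin-dependent kinase inhibitor gene cki-2 by 1.88 (camera adjusted p = 6.3e-05, adjusted p = 0.597 with an estimated correlation). Of 27 DNA replication genes 7 rose, or 12 adjusted over the list alone, with orc-1 rising by 2.14 and the replicative helicase gene mcm-7 by 1.56 (camera adjusted p = 8.8e-06, adjusted p = 0.597 with an estimated correlation). The E2F and DP genes efl-1 and dpl-1 rose by 1.76 and 2.37 and lin-9 of the DREAM complex by 1.21, while the list of 17 lin-35-related repressors was not shifted (camera adjusted p = 0.292). Of 20 histone genes 4 fell, or 9 adjusted over the list alone, his-59 by 1.04 (camera adjusted p = 8.8e-06, adjusted p = 0.576 with an estimated correlation). The neuronal transcription factor gene egl-46 fell by 2.73 ± 0.32, with 1 of 2 lin-35 samples below 5, the dendrite receptor gene dma-1 by 2.45 ± 0.21 and the transcription factor gene mxl-3 by 2.80. Of 75 neuropeptides 1 rose and 5 fell, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.0321, adjusted p = 0.778 with an estimated correlation). The 61 collagens were shifted down with 0 passing, also adjusted over the list alone (camera adjusted p = 0.00037, adjusted p = 0.71 with an estimated correlation).

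In the lin-35 mutant 449 genes rose and 127 fell (limma, adjusted p under 0.05), which is 78% rises, against 63.3% after quantile normalisation and 69.1% after subtraction of array medians. The median change of all genes was 0.01 in the deposited values, -0.12 after quantile normalisation and -0.10 after subtraction. The count of 576 became 379 without lin-35 replicate 1 and 2 more than that without lin-35 replicate 2, and 295 genes passed with wild-type replicate 3 as the only control.

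**Figure D4:**
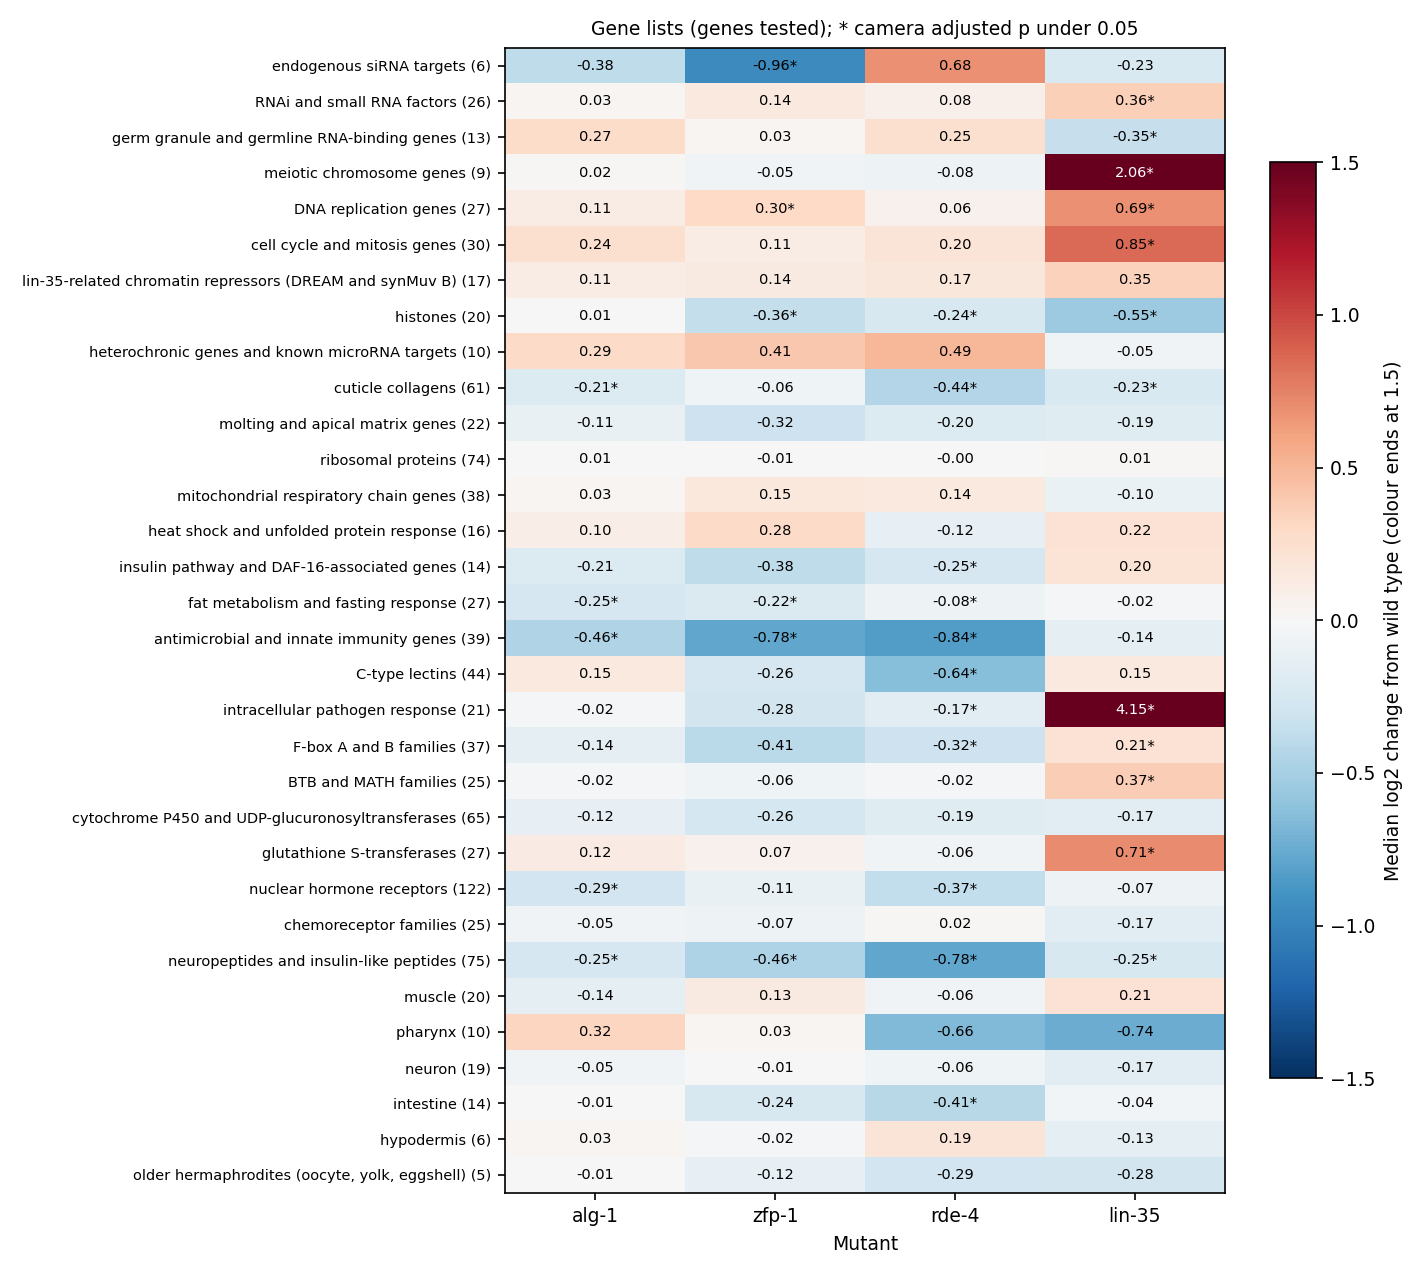
Median log2 change from wild type of the gene lists and marker lists with at least 3 genes tested, per mutant, with the number of genes tested in parentheses and an asterisk where camera gave an adjusted p under 0.05. Genes below 5 in all other groups were tested only if high in the remaining group. The intracellular pathogen response has a median of 4.15 in the lin-35 mutant, and the endogenous siRNA targets have 0.68 in the rde-4 mutant and -0.96 in the zfp-1 mutant; for the germ granule list in the lin-35 mutant the median is -0.35 and the tested shift is upwards.

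The 4 comparisons were then set side by side to ask which genes changed alike. In all 4 mutants 12 genes rose and 13 fell, and 35 rose and 84 fell in at least 3. This excess of shared falls was not stable: 244 rose and 174 fell without wild-type replicate 3, 49.8% of 207 genes rose without alg-1 replicate 2, and 192 rose and 184 fell with 15 arrays as replicates. K10D11.5 rose by 4.7, 4.98, 4.67 and 5.23 in the alg-1, zfp-1, rde-4 and lin-35 mutants, from 3.87 ± 1.76 (SD, n = 3) in wild type, where 2 of 3 samples lay below 5 and leave the size of the rise uncertain. Other rises in all 4 were those of the deubiquitinase gene otub-2 (1.97 to 2.69), the ubiquitin ligase gene mgrn-1 (1.86 to 2.19), the spindle checkpoint gene mdf-2 (1.61 to 2.73) and the helicase gene helq-1 (1.59 to 1.83, with 1 of 3 wild-type samples below 5). The lysozyme gene lys-10 fell from 6.05 ± 2.13 (SD, n = 3) in wild type, with 1 of 3 samples below 5, to below 5 in every mutant sample, at least 2.06-fold lower. lipl-1, lys-4, C23G10.11 and T22F3.11 fell in the alg-1, zfp-1 and rde-4 mutants, and their log2 differences in the lin-35 mutant, -0.78, -2.02, -2.0 and -2.39, did not pass the test.

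Falls were shared by 122 genes between the zfp-1 and rde-4 mutants, by 105 between alg-1 and rde-4 and by 94 between alg-1 and zfp-1. With lin-35, the alg-1, zfp-1 and rde-4 mutants shared 23, 46 and 35 falls. Shared rises numbered 22 for alg-1 and zfp-1, 55 for alg-1 and rde-4 and 65 for zfp-1 and rde-4, and 25, 25 and 60 with lin-35. Calls independent between mutants would give 1.18, 5.93, 7.02, 4.83, 5.71 and 28.6 shared rises, in the same order. The 60 for rde-4 and lin-35 thus partly reflect their long lists of 552 and 449 rises. Between these mutants 14 genes passed in opposite directions, against 2 to 8 in the other pairs. All comparisons used the same 3 wild-type samples, which alone makes log2 changes covary. Of 100 simulations of unchanged groups, 1 had any gene shared by at least 3 mutants, and the number shared had a median of 0 and a maximum of 12. The draws also let 1 sample's residuals enter several groups. With no gene changed, few genes can pass the Benjamini-Hochberg adjustment, which keeps simulated sharing near 0. The real fits called 271 to 961 genes, so their p cutoff was laxer. The simulated counts therefore do not show how many shared genes the common wild-type samples could give. For rises and falls together the simulated median was 0 for each pair of mutants. The simulated maximum was 115 for alg-1 and lin-35, above the 25 rises and 23 falls seen there. It was 0 for alg-1 and zfp-1, 12 for alg-1 and rde-4, 1 for zfp-1 and rde-4, 0 for zfp-1 and lin-35 and 14 for rde-4 and lin-35. The 119 genes became 62, 41 or 418 without wild-type replicate 1, 2 or 3, 35 or 39 without zfp-1 replicate 1 or 2, 60, 207 or 60 without alg-1 replicate 1, 2 or 3, and 8 with wild-type replicate 3 as the only control.

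Direct contrasts set the means of 2 mutants against each other, with wild type entering only the estimate of spread. srw-85 was higher in the alg-1 mutant (9.56 on average) than in the zfp-1 and rde-4 mutants (2.70 and 2.55). acdh-1 was lower in the alg-1 mutant than in the rde-4 mutant, 3.09 against 12.96, and T19C9.8 was lower in the rde-4 mutant than in the alg-1 mutant. cpr-2 differed between the zfp-1 mutant (7.45) and each of the rde-4 (2.54) and lin-35 mutants. E01G4.5 and lido-11 were higher in the rde-4 mutant than in the zfp-1 and lin-35 mutants, and ddn-1, pgl-1 and inx-22 were higher in the lin-35 mutant than in each other mutant. The alg-1 and zfp-1 mutants differed in 61 genes, alg-1 and rde-4 in 88 and zfp-1 and rde-4 in 118 (limma, adjusted p under 0.05). The lin-35 mutant differed from alg-1 in 601 genes, from zfp-1 in 543 and from rde-4 in 984. Without zfp-1 replicate 1 or 2, 23 or 18 genes differed between alg-1 and zfp-1, 27 or 33 between zfp-1 and rde-4, and 270 or 311 between zfp-1 and lin-35. Without alg-1 replicate 1 the counts against zfp-1, rde-4 and lin-35 were 33, 54 and 397, and without alg-1 replicate 3 or rde-4 replicate 1 the alg-1 and rde-4 mutants differed in 46 genes. Without lin-35 replicate 1 the counts against alg-1, zfp-1 and rde-4 were 339, 347 and 465.

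Some lists were not shifted in any mutant by camera. The heterochronic, molting, heat shock, respiratory chain, cytochrome P450, chemoreceptor and older-hermaphrodite lists had camera adjusted p values of 0.0734 or more, and only 1 sperm gene was expressed highly enough to be tested. With fry some of these passed: the older-hermaphrodite list upwards in lin-35 (adjusted p = 2.2e-05), and the chemoreceptors, which include srw-85, downwards in zfp-1 and rde-4 (0.0135 and 0.0216) and upwards in lin-35 (0.0049). In lin-35 the medians of the older-hermaphrodite list and the chemoreceptors were -0.28 and -0.17, so the upward results rest on some members. Of the older-hermaphrodite genes cpg-2 alone passed, and 5 chemoreceptors rose and 3 fell. No ribosomal protein gene of 74 tested passed in the alg-1, zfp-1 or rde-4 mutant, and rpl-11.1 fell by 1.33 in the lin-35 mutant. Medians of the muscle, neuron and hypodermis markers lay between -0.17 and 0.21, and fry moved the hypodermis markers upwards in rde-4 and downwards in lin-35 (adjusted p = 0.0377 and 0.0316). The pharynx markers had medians of -0.66 in the rde-4 mutant and -0.74 in the lin-35 mutant, with camera adjusted p = 0.0958 and 0.0988. The intracellular pathogen response list, which rose in the lin-35 mutant, was shifted down in the rde-4 mutant with 0 of 21 genes passing, also adjusted over the list alone (median -0.17, camera adjusted p = 0.0386, adjusted p = 0.498 with an estimated correlation).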

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

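The tests of the shared changes, of srw-85 and of the lin-35 genes, and the counts over other splits of the samples, were set down only after the results were seen.

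Direct tests of the difference between mutants singled out 61 genes between alg-1 and zfp-1, 88 between alg-1 and rde-4, 601 between alg-1 and lin-35, 118 between zfp-1 and rde-4, 543 between zfp-1 and lin-35 and 984 between rde-4 and lin-35. Some genes passed in opposite directions in different mutants: E01G4.5 rose by 2.85 in rde-4 and was at least 2.70-fold lower in lin-35. F43C11.7, chosen after its values were seen, lay at 6.80 in wild type, 5.44 in alg-1, 4.30 in zfp-1, 4.32 in rde-4 and 8.63 in lin-35. Without alg-1 replicate 1 the alg-1 counts were 33, 54 and 397; without zfp-1 replicate 1 or 2 the zfp-1 counts were 23 or 18 against alg-1, 27 or 33 against rde-4 and 270 or 311 against lin-35. Without alg-1 replicate 3 or rde-4 replicate 1 the count for alg-1 and rde-4 was 46, and without lin-35 replicate 1 the lin-35 counts were 339, 347 and 465.

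Among probe sets that match several genes or none, which no comparison used, 499 passed the filter and were tested, and 19 of these changed in the alg-1 mutant, 24 in zfp-1, 51 in rde-4 and 58 in lin-35. Of probe sets with a single gene, 2.77%, 3.87%, 10.2% and 6.15% changed.

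For the counts of changed genes, the 6 samples of 2 groups of 3 can be split in only 10 ways, too few for a share under 0.05. For alg-1 against wild type the real grouping gave 271 genes and was matched by 1 of the 10 splits, itself; the highest other gave 185 and put alg-1 replicate 2 with wild-type replicates 1 and 2. For rde-4 against wild type the real grouping gave 961 and the highest other 3, and for alg-1 against rde-4 they gave 88 and 1.

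The first pattern weighed is the set of genes that changed alike in at least 3 mutants, such as lipl-1, lys-4 and K10D11.5. The covariance of log2 changes was above the highest of 100 simulations of unchanged groups in 1 of the 6 pairs of mutants, zfp-1 and rde-4 (0.36 against 0.301). The simulations drew the residuals of whole samples with replacement, so 1 sample's residuals could enter several groups and add covariance. The simulated highest thus mixes shared controls with repeated samples. For the other pairs it cannot tell how much shared controls account for. Genes found with wild-type replicates 1 and 2 alone (418) kept 0.364 of their shift against replicate 3, in the same direction for 91.4%. The 95% bootstrap interval over genes was 0.337 to 0.396, which leaves out the spread between samples, as 1 sample was held out. The same ratio was 0.897 for replicate 1 and 1.07 for replicate 2. A state of wild-type replicates 1 and 2, for example in feeding or age, may therefore have enlarged the shared changes, and it and a common response of the mutants cannot be told apart with 3 wild-type samples.

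The second pattern is the loss of srw-85 signal in the zfp-1 and rde-4 mutants. A fall of chemoreceptors as a class was weighed on the 7 others that lay at 6 or more in every wild-type sample. Their median change over both mutants was -0.19 (bootstrap interval over genes -0.96 to -0.02), and 0 of them passed as lower in both. The bootstrap resampled genes and leaves out the spread between samples, so its bound near -1 cannot decide on a 2-fold fall. A fall of the class therefore stays open, and srh-271 fell by 1.92 in zfp-1. A sequence variant carried by both strains could remove the probed sequence: 0 of the 5 samples reached a value of 5, but the 5 expressed neighbours of srw-85 kept their signal, and srw-85 was the only gene that was off in exactly these 2 mutants. A small variant and a shared loss of expression cannot be told apart on arrays, since no sequence was read.

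The third pattern is the rise of germline and intracellular pathogen response genes in the lin-35 mutant. Adult or oocyte-bearing animals in the samples are argued against by 28 yolk and major sperm protein genes. Their median difference from wild type was -0.0648 (bootstrap interval over genes, not samples, -0.18 to -0.05). Their highest level was 5.1, against a median of 10.1 for the 10 germline genes that rose. The eggshell gene cpg-2 rose, while the 4 other tested oocyte, yolk and eggshell markers did not pass (fry adjusted p = 2.2e-05 upwards for the 5, camera adjusted p = 0.942). An infection of the cultures and a change of larval age were not tested and stay open, as does the unc-13 mutation, so a release of these genes by loss of lin-35 is a hypothesis.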

How the results depend on the processing

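The fits with wild-type replicate 3 as the only control and with alg-1 replicates 1 and 3 as a single sample were chosen after seeing the data. Genes that passed against wild type kept their direction in every alternative fit by gene that tested them. For most alternatives this was fixed in advance. All mutant samples lay beyond all wild-type samples for 271 of 271 called genes in alg-1, 363 of 363 in zfp-1, 956 of 961 in rde-4 and 576 of 576 in lin-35. Omitting samples could therefore hardly reverse a direction, and other thresholds, priors or filters leave the log2 changes as they are. Of 17118 genes 8653 were tested, and changes among the others, with signal below the filter, would be missed. Of 7617 repeats of named genes 6376 stayed past the threshold and 1241 did not, as did 519 and 151 of 670 for shared genes. Of 924 repeats of lists, 782 kept their direction and their side of the threshold. Another 128 no longer passed, 12 newly passed and 2 reversed. Except where the alternative itself tests more genes or fewer samples, the cause was not tested. Without a filter, which tests more genes, the alg-1, zfp-1 and rde-4 counts were 137, 167 and 376, those between alg-1 and rde-4 and between zfp-1 and rde-4 were 47 and 76, and 62 genes were shared. With 15 arrays as replicates, which counts repeated arrays as populations, the counts were 449, 1249 and 1109 for alg-1, zfp-1 and lin-35, 230, 186, 1001, 355 and 1120 between alg-1 and zfp-1, alg-1 and rde-4, alg-1 and lin-35, zfp-1 and rde-4 and zfp-1 and lin-35, and 376 shared. With only the mutant and wild type in a fit, 128, 101, 195 and 310 genes passed for alg-1, zfp-1, rde-4 and lin-35 and 30 were shared. At an adjusted p under 0.01 these were 58, 80, 151 and 339, and 23 shared. At an adjusted p under 0.05 and at least 2-fold, 632 rde-4 genes passed. With wild-type replicate 3 as the only control they were 16, 21, 33 and 295, and 8 shared, and 3, 4 and 8 lists were shifted in alg-1, zfp-1 and rde-4. With alg-1 replicates 1 and 3 as a single sample, 67 genes passed for alg-1, 37, 48 and 395 between it and zfp-1, rde-4 and lin-35, and 62 were shared. camera with an estimated correlation left 0, 0, 0 and 1 lists in alg-1, zfp-1, rde-4 and lin-35, and fry 1 in alg-1. Of the lists, the median of the F-box A and B families in the lin-35 mutant reversed to -0.061 without a filter (adjusted p = 0.417), and that of the neuropeptides and insulin-like peptides in the lin-35 mutant to 0.041 with wild-type replicate 3 alone (adjusted p = 0.963).

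Leaving out each biological sample gave 67 to 496 genes for alg-1, 49 to 854 for zfp-1, 230 to 1452 for rde-4, 379 to 781 for lin-35 and 35 to 418 shared. Each of these highest counts came without wild-type replicate 3. Between mutants the ranges were 18 to 89 for alg-1 and zfp-1, 46 to 103 for alg-1 and rde-4, 339 to 724 for alg-1 and lin-35, 27 to 144 for zfp-1 and rde-4, 270 to 632 for zfp-1 and lin-35 and 465 to 1128 for rde-4 and lin-35. Shifted lists numbered 5 to 8, 5 to 10, 10 to 18 and 8 to 14. The change of rde-4 in its mutant lay between -3.04 and -2.89, that of lin-35 between -1.99 and -1.23, alg-1 between -1.90 and -0.69, zfp-1 between -0.07 and 0.10 and unc-13 between -0.26 and -0.06. A group left with 1 sample was assumed to vary like the others. With the replicate number as a block, 856 zfp-1 genes passed (407 rises, 449 falls), 239 were shared and 12 lists were shifted in zfp-1. The labels share only numbers, and whether these pair the samples stays open: 4 of 9 samples correlated best with their own number, and 14 of 23 pairs of the same number correlated over 0.1.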

Other observations

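The tests of neighbouring genes, of calls per chromosome, of genes near the mutated genes and of the propionate shunt were set down only after the results were seen, while the chromosome lists were planned. The genes of this part that the naming rule does not cover were also chosen after their values were seen.

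In the rde-4 mutant a run of tested genes next to each other in assembly WBcel235 rose together. lido-8, lido-9, lido-10 and lido-12 rose by 2.12, 2.12, 1.95 and 2.40 beside lido-11, which was at least 3.74-fold higher. lido-11 was the only gene below 5 in all samples of the other 4 groups, at or above 5 in all rde-4 samples and at least 2 apart between them. In the lin-35 mutant lido-12 fell by 1.07. The chemoreceptor genes srd-4 and srh-16 were at least 6.76-fold and 3.67-fold higher in the lin-35 mutant, where 5 of 25 tested chemoreceptors rose and 3 fell, and the lectin gene clec-60 rose by 4.61. egl-46 and flp-21 fell by 2.73 and 2.27 in the lin-35 mutant and by 2.22 and 2.93 in the zfp-1 mutant, with 1 of 2 lin-35 samples below 5 for egl-46. Of the 19 neuron markers 0 passed in either (camera adjusted p = 0.405 and 0.903). The molting regulator nhr-23 rose by 1.69 in alg-1 and 1.42 in rde-4, and the phosphatase gene cdc-25.2 rose by 1.68 in rde-4 and fell by 2.11 in lin-35.

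K10D11.5 had values of 2.69, 5.89 and 3.03 in the wild-type samples and of 8.26 to 9.38 in the 10 mutant samples. lys-10 had values of 3.87, 8.12 and 6.15 in wild type and of 1.97 to 2.78 in the mutants. acdh-1 varied within groups, with 13.92, 14.35 and 10.61 in the rde-4 samples and 13.39 and 9.44 in the lin-35 samples.

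Tested genes that rose next to each other along the chromosomes of assembly WBcel235 were more numerous in the lin-35 mutant than after 10000 permutations of the calls, 77 pairs or 3.32 times the permuted mean (p = 1e-04, the smallest the permutations can give, adjusted p = 0.0008). Examples are pgl-1 with him-3, inx-22 with inx-21, pals-37 with pals-38 and pals-27 with pals-28. The ratio was 1.61 for falls in lin-35, 1.48 for rises and 1.98 for falls in rde-4, 2.17 and 2.32 in zfp-1 and 1.01 and 1.64 in alg-1. Of these, the rises and falls in rde-4 (adjusted p = 0.0054 and 0.0008) and the falls in zfp-1 (adjusted p = 0.0019) passed. Operons, duplicated genes and chromatin domains were not separated. In addition, 106 genes below 5 in all samples of the other groups, pgl-1, him-3 and inx-22 among them, were tested through lin-35 alone. Such genes enter already high and can be neighbours of each other, which permuting the calls of tested genes does not reproduce. The excess of neighbouring rises in lin-35 is thus conditioned on the rise.

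Rises in the lin-35 mutant were depleted on the X chromosome, with 24 of 1289 genes, or 1.86%, against 5.77% of genes on the autosomes (odds ratio 0.31, Fisher's exact test, adjusted over 48 tests, p = 4.5e-09). Rises in rde-4 were depleted there too (3.26% against 6.94%, odds ratio 0.451, adjusted p = 2.2e-06) and its falls enriched (odds ratio 1.42). Falls in alg-1, zfp-1 and rde-4 were enriched on chromosome V (odds ratios 1.70, 1.86 and 1.72) and depleted on I (0.453, 0.517 and 0.427). These mutants were set against the same wild-type samples and shared 94 to 122 falls per pair, so the results are not independent. Rises in rde-4 and lin-35 were enriched on I (1.61 and 1.53), and rises in rde-4 depleted on V (0.576). Genes below 5 in all groups but lin-35 were tested only if high there. The lin-35 shares of rises, on X as well, are thus conditioned on the rise. The other 36 of the 48 tests did not pass. The 48 tests were not repeated without single samples. As planned lists, X genes were shifted down in lin-35 and rde-4 (camera adjusted p = 0.0361 and 0.0386), chromosome V genes were shifted down in zfp-1 and rde-4 (0.0272 and 0.0167), and chromosome I genes were shifted up in rde-4 (0.0179); adjusted p = 0.314 or more with an estimated correlation.

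Calls close to the mutated genes were counted because a strain may carry linked variants. Of the 200 tested genes around lin-35, 23 changed in its mutant, against 6.53% elsewhere (Fisher's exact test, adjusted p = 0.0363), but against the rest of chromosome I alone, with 7.73%, the exact p was 0.095. For alg-1, zfp-1 and rde-4 the adjusted p values were 0.0661, 0.0661 and 0.495, with 12, 3 and 25 of 200 genes changed near the gene against 259, 360 and 935 of 8452 elsewhere. Of these, zfp-1 had fewer calls nearby than elsewhere, and the upper bounds of its odds ratio and that of rde-4 were 1.02 and 1.76.

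The falls of acdh-1, hphd-1 and nhr-68 in the alg-1 and zfp-1 mutants could be part of a fall of the whole propionate shunt. hach-1 and alh-8, enzymes of the shunt that the naming rule had not named, had median changes of -0.82 in alg-1 and -0.52 in zfp-1, and neither passed in either mutant. The rule names genes by large or significant changes, so enzymes left unnamed are weak by selection. These 2 cannot decide whether the whole shunt fell. Values for hach-1 and alh-8 were -0.56 ± 0.27 (SE) and -1.07 ± 0.44 in alg-1 and -0.44 ± 0.30 and -0.59 ± 0.49 in zfp-1. The enoyl-CoA hydratase gene ech-6 was left out of the shunt genes weighed here, and it fell by 1.89 in alg-1 and by 1.54 in zfp-1.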
